A study of Xenopus laevis with 30 samples.

How the data were processed

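The series holds 30 Affymetrix Xenopus laevis Genome 2.0 arrays, 2 for each of 15 stages, hybridised with biotin-labelled RNA from pooled whole embryos. Per the labels, total RNA was extracted with a lipid tissue column kit and labelled in a single amplification cycle. The deposited values are linear signal intensities per probe set made by the authors with MAS5, per the submitters' processing notes, whose version is not given in the sources used here. In the deposited table all values lie above 0 and every array has the same 2% trimmed mean of 500 units, so each array had been scaled to a common total and no further normalization was applied for the main results. Detection calls were not used here.

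The values were converted to log2. The 96 control probe sets were left out, and of the other 32539, a probe set was tested if both arrays of at least 1 stage lay above their own array's median (the 50th percentile), which kept 23403. Symbols came from GEO's platform annotation: 15495 probe sets had 1 symbol, 279 had several and were not named, and 16765 had none. Of those with 1 symbol, 15384 were found in the RefSeq table of assembly v10.1 by Entrez identifier and 2 had been renamed. The assembly was used for names, and no coordinates are given. L and S copies were joined under 1 symbol, and the probe set with the highest mean over the 30 arrays stood for the gene.

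Stages were compared with limma 3.58.1 in R 4.3.3: 1 linear model over all 30 arrays with a mean per stage and 15 residual degrees of freedom, moderated with a trend and robust settings, and Benjamini-Hochberg adjustment over the probe sets of a comparison at 0.05. An F test covered the 15 stages, 14 tests the neighbouring stages, and 5 tests the intervals from stage 2 to 5, 5 to 11, 11 to 21, 21 to 31 and 31 to 48. With 26 gene lists from textbook knowledge, 25 of which had at least 5 measured members, camera compared each list with the other genes at a preset correlation of 0.01, adjusted over 125 list tests, and again with the correlation estimated. Adjusted p-values of single lists are from camera at the preset correlation unless stated otherwise, those of single genes from limma. Named genes followed a rule: per interval the 7 largest rises and 7 largest falls among called genes whose replicates did not overlap and whose brighter stage exceeded the arrays' median, and up to 3 called members with the largest change from each list fixed for the interval. Changes were ranked by fitted values, which include signals under the array median, so a rank does not order measured folds. The text gives a selection of the genes this rule takes. The groups, tests, lists, naming rule and first set of alternatives were fixed before the data were examined.

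Alternatives were quantile normalization, median centring, no filter, a filter at the 75th percentile, log2 of the signal plus 50, moderation without trend and robust settings, leaving out probe sets ending in _s_at or _x_at, an adjusted p of 0.01, an added 2-fold threshold, the replicate number as a block, the 2 stages compared alone, leaving out each array, and for lists also the mean of all probe sets per gene and fry. Scaling to the 12 poly-A control probe sets and array weights by stage were chosen after seeing the data.

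The fit was tested on simulated data with the real means and with noise set by stage and signal level, in which 200 of 23403 probe sets changed. Of 50 probe sets changed 4-fold, 46 were recovered between stages 2 and 5, 44 between stages 5 and 11, 46 between stages 11 and 21, 44 between stages 21 and 31 and 46 between stages 31 and 48. Among 23203 unchanged probe sets 305, 109, 16, 11 and 9 were called in the same order. Of all calls in the simulation these were 65.7%, 43.1%, 9.70%, 7.14% and 5.45%, above the 5% that the threshold allows in each interval and far above it in the first ones. The simulation held 200 changes, fewer than the calls made in the data, so these counts and shares do not carry over to the data. With array weights by stage the counts for the first intervals were 156 and 77, or 50.8% and 35.2% of all calls in the simulation. A simulation with 1 noise factor per stage gave 285 for stages 2 to 5, and 7 with array weights. Array weights by stage fit that same noise model, so the drop to 7 was built in. A difference in noise between stages is thus enough to give such an excess in simulated data. Whether it does so in the real data was not tested. An earlier simulation that held each probe set at a single level over all stages was replaced because it gave no probe set that is dim in some stages and bright in others.
Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.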

Results

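Total RNA from pooled whole wild-type embryos of the clawed frog Xenopus laevis was measured on 30 Affymetrix arrays, 2 for each of 15 developmental stages from the 2-cell embryo (stage 2) to the feeding tadpole (stage 48). The labels call the arrays of a stage biological replicates, each from a pool of several embryos. Of 32635 probe sets on each array, 23403 were bright enough to be tested, and 12587 of these carried a single gene symbol, which gave 8073 genes with 1 probe set each. The median signal per array ranged from 105.6 to 184.1 arbitrary units, and the number of arrays limits the precision. Log2 signals of the replicates correlated at 0.974 to 0.985 across probe sets, and in all 15 stages the replicates were closer to each other than to any array of another stage. Because signals well under the array median are poorly measured, a fold whose dimmer stage lies under that median is written as "at least N-fold", set against the median signal of that stage's arrays (107 at stage 2 to 183 at stage 48), a chosen floor and not a measured background.

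The signal of the added poly-A control RNA was not constant over the course. The mean of its 12 probe sets was 649 units at stage 11 and 188 at stage 48, a log2 change of -1.78, while the 9 hybridisation control probe sets changed by -0.34 on the log2 scale. Scaling the arrays to these poly-A controls, an alternative chosen after seeing the data, shifted the median log2 change of all tested probe sets from 0.02 to 0.14 between stages 2 and 5, from -0.03 to -0.33 between stages 5 and 11, from -0.02 to 0.79 between stages 11 and 21, from -0.002 to 0.60 between stages 21 and 31 and from -0.13 to 0.25 between stages 31 and 48. It moves every list median below by the same amount within an interval: 0.11, -0.29, 0.80, 0.60 and 0.38 on the log2 scale, in that order. Such scaling also carries the replicate differences of the poly-A controls into every probe set. These ranged from 0.01 at stage 28 to 0.37 at stage 21 on the log2 scale. At stage 21 the median absolute replicate difference of probe sets was 0.14. Whether calls lost under poly-A scaling stem from this was not tested. Every change below is relative to the total signal of the array unless it says otherwise, and a gene list is tested against the other genes. List names stand for sets of genes: signals of whole embryos do not show in which tissue a gene was expressed, or that the named tissue was present. Where no further count is given for a list, the count adjusted over the list alone was the same. Counts are over the tested members, so members dim at all stages or without a named probe set are left out. A member dim at a given stage entered only through a brighter stage, so counts do not describe whole gene families.

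**Figure D1:**
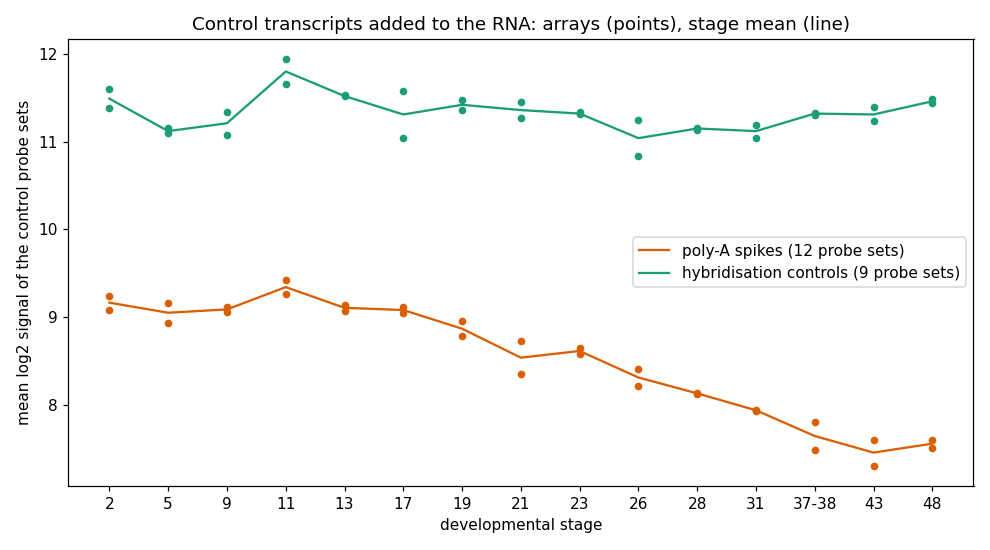
Mean log2 signal of the 12 poly-A control probe sets (orange) and the 9 hybridisation control probe sets (green) by stage, with a point per array and a line through the stage means. The poly-A controls were at 649 units at stage 11 and 188 at stage 48.

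The first question was how much of the transcriptome changed over development. By limma's F test over the 15 stages, 23367 of 23403 probe sets changed at an adjusted p under 0.05, and 22799 of these spanned at least 2-fold in fitted values between their highest and lowest stage. On the deposited scale, signals were highest most often at stage 48 (4446 probe sets) and stage 2 (3440), and also lowest most often at these stages (5175 and 3209). One gene per list was chosen by its fitted range, a ranking that includes signals under the array median and so does not order measured folds. In the muscle list this was myl1, a myosin light chain, highest at stage 48 with 23480 units, at least 181-fold over its lowest stage. In the blood list it was hba2, an alpha globin, highest at stage 48 with 19370 units, at least 141-fold. In the cell cycle list it was ccnb1, a mitotic cyclin, highest at stage 2 with 17700 units, at least 96.5-fold. The linker histone of the oocyte, h1-8, was highest at stage 2 with 9716 units and lowest at stage 43, at least 53.6-fold lower. The epidermal keratin krt12.4 was highest at stage 21 with 18900 units, and ccdc78, of the motile cilia list, also at stage 21 with 380.8 units, at least 3.36-fold over its lowest stage.

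**Figure D2:**
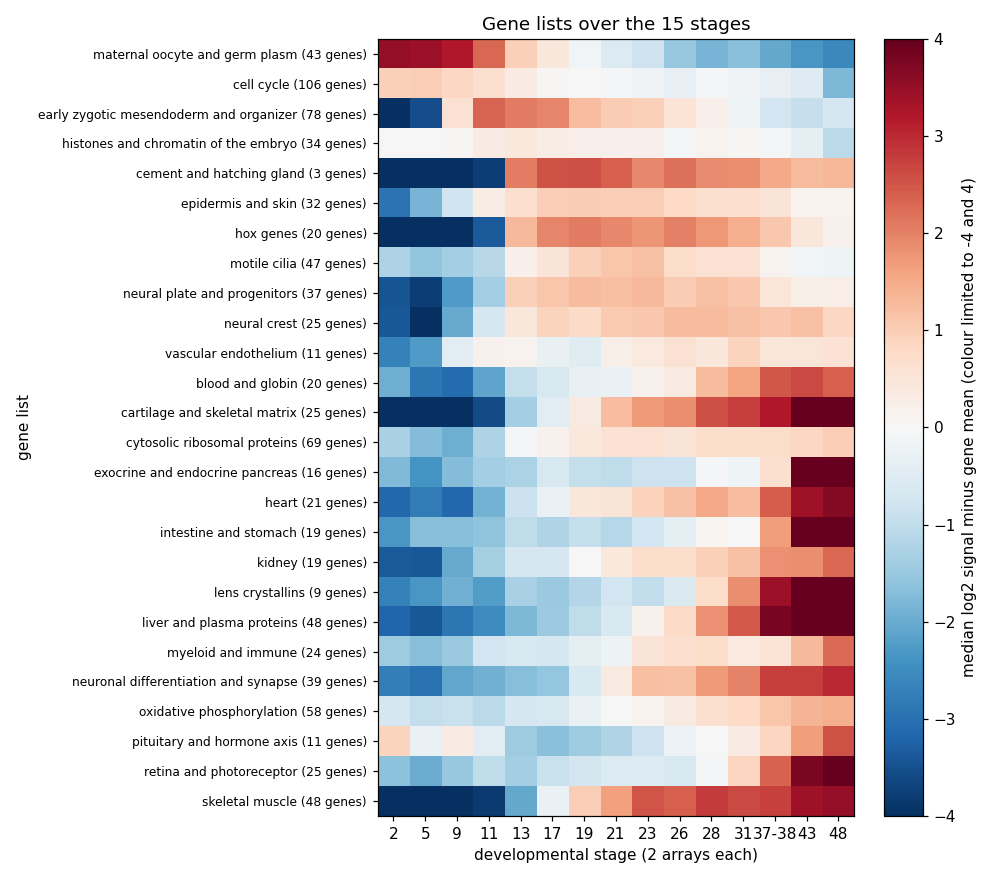
Median over the genes of each list of the log2 signal minus the gene's mean over the 15 stages, with lists as rows in the order of their highest stage, stages as columns and colour limited to -4 and 4. Genes of the maternal list were highest early, and those of the pancreas list at stage 48.

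**Figure D3:**
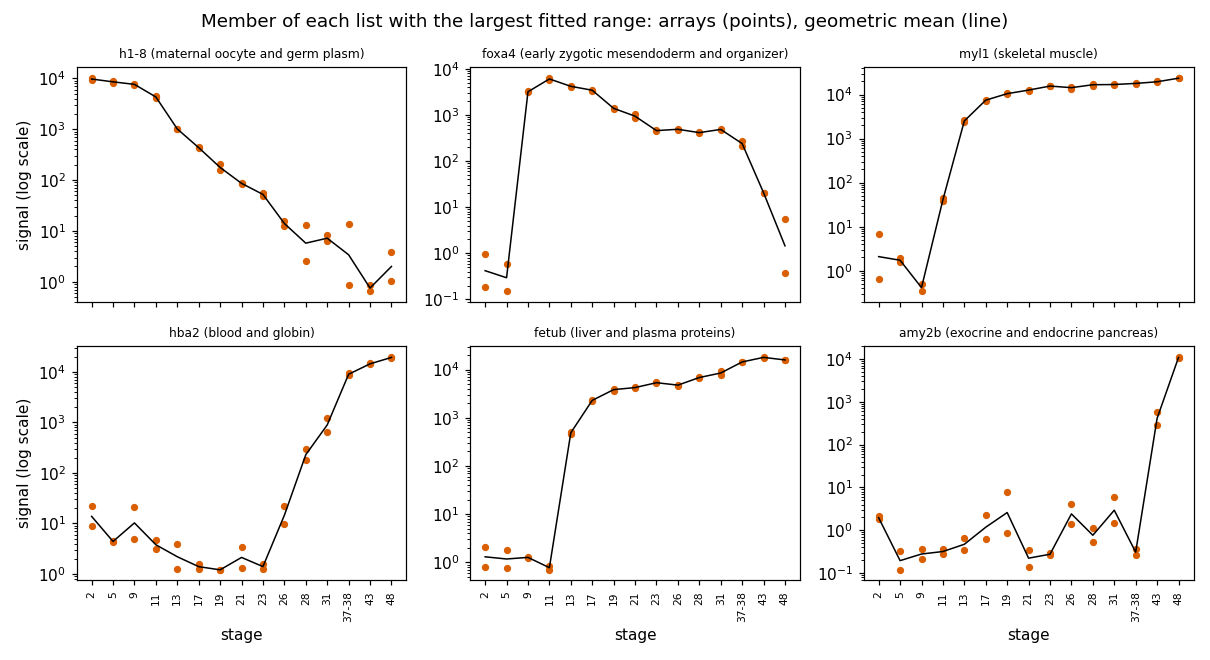
Signal on a log scale against stage for the gene with the largest fitted range in 6 lists, with points for the 2 arrays of a stage and a line through their geometric means. The signal of h1-8 was 9716 units at stage 2 and that of amy2b was 10770 units at stage 48.

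Between neighbouring stages, the step from stage 11 to 13 changed the most probe sets (15965) and the step from stage 9 to 11 the next most (14091). Stages are not evenly spaced in time and the labels give no hours, so counts of steps or intervals give no rate of change. The step from stage 19 to 21 changed 4062 and that from stage 21 to 23 changed 4593, against 5036 and 1444 under poly-A scaling. The last step, from stage 43 to 48, changed 10785 probe sets, of which 6790 were lower in the later stage. Leaving out a single array lowered the stage 19 to 21 count to 1702, without stage 19 replicate 1.

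**Figure D4:**
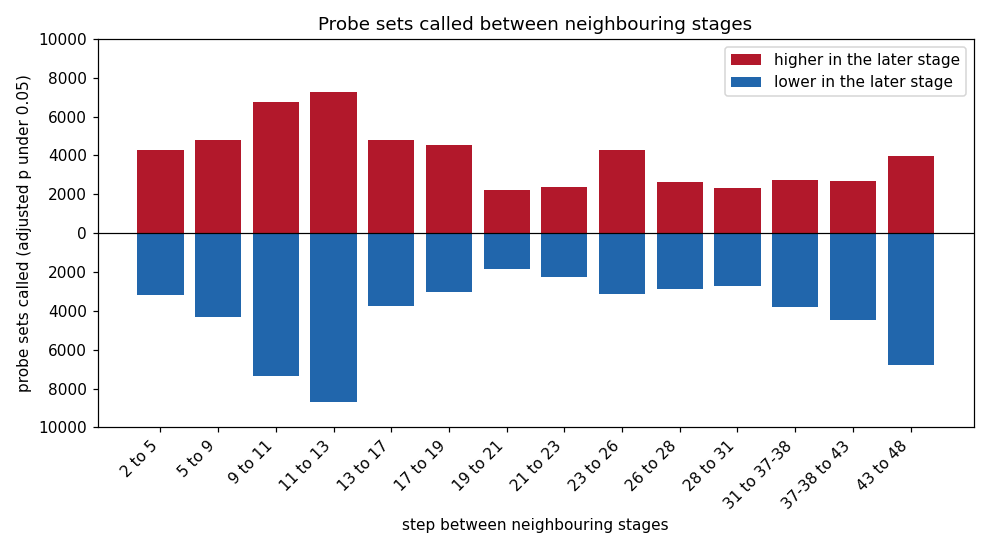
Number of probe sets called by limma at an adjusted p under 0.05 in each of the 14 steps between neighbouring stages, with those higher in the later stage above 0 and those lower below 0. The step from stage 11 to 13 has 15965 calls and that from stage 19 to 21 has 4062.

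From stage 2 to stage 5, the cleavage divisions, 1675 of the 7488 called probe sets changed at least 2-fold. Among the rises, nit2 was at 879.8 units at stage 5, at least 8.2-fold higher, and actr10, a dynactin subunit, was at 841.7 units, at least 7.85-fold higher. The latter was at 112 and 124 units again in the stage 11 replicates. The peroxidase gpx8 rose to 627.8 units, at least 5.85-fold, and the neuropeptide precursor nts to 247.2 units, at least 2.31-fold. The signals of nts and nit2 were under the array median from stage 9 to stage 21. Those of nts were high again at stage 26 (385 and 589 units) and stage 28 (346 and 444 units), and its stage 31 replicates had 4.43 and 110 units. Which parents each pool of embryos came from is not given in the sources used here, so a difference between stages also holds any difference between the parents used. Rises and falls here are changes in array signal, and whether the amount of a transcript or its labelling changed was not tested. Among the falls, the kinase gene pim1 went from 1239 to 293.4 units, a log2 change of -2.08 with SE 0.12 (n = 2 per stage), and the transcription factor gene tfap2e fell from 329.4 units, at least 2.91-fold. Genes of the cytosolic ribosome fell, with 53 of 69 lower and 0 higher (57 and 0 adjusted over the list alone), and so did oxidative phosphorylation genes, with 34 of 58 lower and 8 higher (36 and 11 adjusted over the list alone). Their medians were -0.27 and -0.29 on the log2 scale, and with an estimated correlation between genes the calls were lost (adjusted p = 0.12 and adjusted p = 0.057). The list of histones and embryonic chromatin was called lower too, with 14 of 34 lower and 4 higher (median log2 change -0.11, adjusted p = 0.033, adjusted p = 0.13 with an estimated correlation). Its median of -0.11 turned to 0.003 under poly-A scaling, and the call was also lost with quantile normalization (adjusted p = 0.85) and without stage 2 replicate 2 (adjusted p = 0.11).

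Of the lists fixed for this interval, maternal oocyte and germ plasm genes did not pass (5 of 43 lower, 3 higher; 4 and 2 adjusted over the list alone, median log2 change -0.10, adjusted p = 0.39), nor did cell cycle genes (26 of 106 lower, 20 higher; 29 and 25 adjusted over the list alone, median log2 change -0.09, adjusted p = 0.37). Both medians changed sign under poly-A scaling (0.01 and 0.03) and with quantile normalization (0.02 and 0.01). In the cell cycle list, the mitotic kinesin kif11 fell from 5191 to 2674 units and thymidylate synthase, tyms, rose from 604.7 to 1139 units. In the maternal list eif4enif1, which binds a cap-binding protein, rose from 1675 to 2669 units. Early mesendoderm genes did not pass either (20 of 78 higher, 6 lower; 20 and 7 adjusted over the list alone, median log2 change 0.14, or 0.03 with 50 units added and 0.25 under poly-A scaling, adjusted p = 0.24), and their members with the largest fitted changes, fst, nodal3.1 and mespa, were under the array median in both stages, so no fold is given. Another probe set of mespa was called in the opposite direction. The calls for kpna7 (707.8 and 1218 units) and zp4 (1432 and 928 units), of the maternal list, were lost with array weights by stage, an alternative chosen after seeing the data, at adjusted p = 0.072 and adjusted p = 0.069. That for kpna7 was also lost with quantile normalization (adjusted p = 0.062), and that for zp4 under poly-A scaling (adjusted p = 0.12).

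In this interval limma called 7488 probe sets, 4287 higher and 3201 lower at stage 5. In simulated data 305 of 23203 unchanged probe sets were called between stages 2 and 5, beside 159 of 200 changed ones. This is no estimate of the false calls in the data, where more calls let the adjustment admit larger p-values. Without adjustment 8.92% of the simulated unchanged probe sets had a limma p under 0.05. With array weights by stage, chosen after seeing the data, the real count was 5378. Of the calls, 57.3% were higher, against 75.9% under poly-A scaling, which gave 4198 calls, and 43.2% with median centring.

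From stage 5 to stage 11, when the embryo's own genome is switched on and gastrulation begins, genes of the mesendoderm, neural plate and epidermis lists rose. Of the list of early zygotic mesendoderm and organizer genes, 69 of 78 were higher and 4 lower (70 and 4 adjusted over the list alone). The median log2 change was 6.83, or 4.05 with 50 units added to each signal (adjusted p = 7.8e-19, adjusted p = 6.6e-06 with an estimated correlation). The forkhead factor gene foxa4 was at 6026 units at stage 11, at least 53.1-fold higher. The gene gs17 was at 15000 units, at least 132-fold higher, and cdx1, a posterior homeobox gene, at 5534 units, at least 48.8-fold higher. The Wnt target gene sp5l reached 21000 units, at least 185-fold higher. Genes of the neural plate rose, with 25 of 37 higher and 2 lower (26 and 2 adjusted over the list alone, median log2 change 1.39, or 0.56 with 50 units added, adjusted p = 7.2e-06), among them otx2 and zic1, at least 20.5-fold and 80.1-fold. Epidermal genes rose, with 23 of 32 higher and 6 lower (24 and 6 adjusted over the list alone, median log2 change 1.07, adjusted p = 6.5e-05), among them the keratin krt70 at 14880 units, at least 131-fold higher.

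Neural crest genes were also called higher (16 of 25 higher and 5 lower, median log2 change 2.58, or 0.63 with 50 units added, adjusted p = 0.0030), with id3, an inhibitor of DNA binding, at 17310 units and at least 153-fold higher. The kidney list was called higher with 11 of 19 higher and 1 lower (median log2 change 1.75, or 0.23 with 50 units added, adjusted p = 0.024). Its call was lost with a filter at the 75th percentile (adjusted p = 0.099).

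Maternal transcripts fell over the same interval, with 25 of 43 lower and 6 higher (median log2 change -0.91, adjusted p = 0.018). The translational regulator cpeb1 fell from 7086 units, at least 59.1-fold. The gene fbxo43, an inhibitor of the anaphase-promoting complex, fell from 6651 units, at least 55.5-fold. The gene btg4, which takes part in maternal mRNA decay, fell from 11380 to 178 units, a log2 change of -6.00 with SE 0.37 (n = 2 per stage). Outside the lists the cochaperone dnajc9 fell from 5695 units, at least 47.5-fold, and nit2 and nts, which had risen by stage 5, fell at least 7.34-fold and 2.06-fold. Cell cycle genes divided: 56 of 106 were lower and 29 higher (56 and 30 adjusted over the list alone), and the list's call (median log2 change -0.33, or -0.63 under poly-A scaling, adjusted p = 0.022) was lost with an estimated correlation (adjusted p = 0.42). In that list ccnd1, cyclin D1, rose from 153.1 to 4831 units, a log2 change of 4.98 with SE 0.11 (n = 2 per stage). Ribosomal protein genes were called higher (49 of 69 higher and 3 lower, 50 and 4 adjusted over the list alone, median log2 change 0.42, or 0.13 under poly-A scaling, adjusted p = 2.8e-06), a call lost with an estimated correlation (adjusted p = 0.39). The chromatin list was called higher (18 of 34 higher and 6 lower, 18 and 7 adjusted over the list alone, adjusted p = 0.037) and lost its call with an estimated correlation (adjusted p = 0.14). Its median of 0.26 turned to -0.04 under poly-A scaling.

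In all, limma called 15674 probe sets between stages 5 and 11, 7715 higher and 7959 lower. Of these calls 49.2% were higher, against 34.4% under poly-A scaling, and in simulated data 109 of 23203 unchanged probe sets were called, beside 144 of 200 changed ones. The simulation held fewer changes than the data, so this count does not carry over. Without adjustment 7.37% of the simulated unchanged probe sets had a limma p under 0.05. With array weights by stage the real count was 14893. Of 9 list calls, 6 held with an estimated correlation.

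From stage 11 to stage 21, through neurulation, skeletal muscle and hox genes rose. Of 48 skeletal muscle genes 42 were higher and 1 lower. Their median log2 change was 5.64, or 3.42 with 50 units added (adjusted p = 3.1e-10, adjusted p = 2.3e-04 with an estimated correlation). On a probe set shared with similar transcripts, the myosin heavy chain myh4 was at 16260 units, at least 136-fold higher. The myosin light chain mylpf was at 14170 units, at least 118-fold higher. All 20 hox genes tested, of 52 in the list, were higher (median log2 change 5.16, or 2.83 with 50 units added, adjusted p = 7.8e-06). Among these regulators of position along the body axis, hoxb9 was at 2261 units, at least 18.9-fold higher. Motile cilia genes rose, with 39 of 47 higher and 5 lower, such as tekt2, a tektin of the axoneme, at least 12.8-fold. The list's median log2 change was 2.06 (adjusted p = 7.5e-07, adjusted p = 0.022 with an estimated correlation). Cartilage and matrix genes rose in 21 of 25 cases with 0 lower (median log2 change 4.98, or 2.49 with 50 units added, adjusted p = 6.5e-05). The collagen col2a1, also on a shared probe set, was at 5507 units, at least 45.9-fold higher. Neuronal genes rose, with 30 of 39 higher and 2 lower (median log2 change 2.69, or 0.98 with 50 units added, adjusted p = 3.7e-04). Neural crest genes rose as well, with 18 of 25 higher and 3 lower (median log2 change 1.43, adjusted p = 0.024), including sox10, at least 4.30-fold. Poly-A scaling ended that list's call (adjusted p = 0.081), while its mean minus that of the other genes stayed at 1.58.

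The neural plate list, with 24 of 37 higher and 10 lower, did not pass (median log2 change 3.06, or 1.28 with 50 units added, adjusted p = 0.15), although pax6, an eye and neural tube regulator, rose to 2559 units, at least 21.3-fold. The cement and hatching gland list had 3 measured members of 23, too few to test. Of these agr2, a cement gland gene, reached 13560 units, at least 113-fold higher. The gene pitx1 reached 326.6 units, at least 2.72-fold higher, and dlx3 was at 2440 and 2334 units (adjusted p = 0.93). Heart genes (13 of 21 higher and 2 lower, median log2 change 3.13, or 0.89 with 50 units added, adjusted p = 0.033) and liver genes (27 of 48 higher and 7 lower, 27 and 6 adjusted over the list alone, median log2 change 1.44, or 0.57 with 50 units added, adjusted p = 0.028) were called higher. Both calls were lost with an estimated correlation (adjusted p = 0.11 and adjusted p = 0.097). The plasma protein gene fetub was at 4227 units, at least 35.3-fold higher. Ribosomal protein genes were called higher, 68 of 69 with 0 lower (69 and 0 adjusted over the list alone, median log2 change 1.76, adjusted p = 1.0e-20), a call lost with an estimated correlation (adjusted p = 0.11). Oxidative phosphorylation genes were called higher too, 48 of 58 with 5 lower (median log2 change 0.98, adjusted p = 2.1e-08), and this call was lost with an estimated correlation as well (adjusted p = 0.073).

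Maternal and early mesendoderm genes fell. Maternal genes were lower in 39 of 43 cases and higher in 1 (median log2 change -2.82, or -2.10 with 50 units added, adjusted p = 5.0e-08). Early mesendoderm and organizer genes were lower in 47 of 78 and higher in 12 (46 and 12 adjusted over the list alone, median log2 change -1.25, adjusted p = 0.0086). Under poly-A scaling these medians were -2.02 and -0.44. The Nodal coreceptor gene tdgf1.3 fell from 7839 units, at least 54.7-fold. The gene cer1, for a secreted antagonist of Nodal, BMP and Wnt signals, fell from 7256 units, at least 50.6-fold. The mesendoderm homeobox gene mix1 fell from 2811 units, at least 19.6-fold. Cell cycle genes were lower in 66 of 106 and higher in 27 (67 and 27 adjusted over the list alone, median log2 change -0.60, adjusted p = 0.0029), a call lost with an estimated correlation (adjusted p = 0.33). Their median turned to 0.21 under poly-A scaling.

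This interval had the most calls of the 5, 18627, with 9296 higher and 9331 lower. Of these 49.9% were higher, against 77.1% under poly-A scaling. Of 13 list calls, 8 held with an estimated correlation.

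From stage 21 to stage 31, the tailbud period, genes of the oxidative phosphorylation, liver and neuronal lists rose. Oxidative phosphorylation genes were higher in 56 of 58 cases and lower in 1. Their median log2 change was 0.87 (adjusted p = 1.2e-20, adjusted p = 0.0076 with an estimated correlation). Liver and plasma protein genes were higher in 35 of 48 and lower in 2 (37 and 3 adjusted over the list alone, median log2 change 2.50, or 1.55 with 50 units added, adjusted p = 7.2e-06). The retinol carrier rbp4 was at 2197 units, at least 15.3-fold higher, and the fibrinogen chain fga at 1298 units, at least 9.05-fold higher. The gluconeogenic enzyme gene g6pc1.1 rose to 2371 units, at least 16.5-fold. Neuronal genes were higher in 29 of 39 and lower in 1 (median log2 change 1.74, adjusted p = 2.7e-05), such as the synaptic regulator cplx1 at 1073 units, at least 7.48-fold higher. Globin and other blood genes were higher in 11 of 20 and lower in 3 (12 and 3 adjusted over the list alone, median log2 change 1.15, or 0.63 with 50 units added, adjusted p = 0.027), with hbd, a globin, at 3082 units and at least 21.5-fold higher. The list's call was lost with an estimated correlation (adjusted p = 0.051).

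Lens crystallin genes were called higher (6 of 9 higher and 0 lower, 7 and 0 adjusted over the list alone, median log2 change 2.49, or 1.66 with 50 units added, adjusted p = 0.033), a call lost with an estimated correlation (adjusted p = 0.14). Of these, cryba1 was at 939.1 units, at least 6.55-fold higher. Skeletal muscle genes were called higher as well (21 of 48 higher and 4 lower, median log2 change 0.84, adjusted p = 0.037), a call also lost with an estimated correlation (adjusted p = 0.073). The troponin tnnt3 went from 536.6 to 6920 units with a log2 change of 3.69 and SE 0.22 (n = 2 per stage). The pituitary and hormone list was called higher (7 of 11 higher and 0 lower, median log2 change 1.21, or 0.78 with 50 units added, adjusted p = 0.042) and lost its call with an estimated correlation (adjusted p = 0.11). Single arrays decided these calls: without stage 31 replicate 2 the muscle and pituitary lists had adjusted p = 0.076 and adjusted p = 0.053, and without stage 21 replicate 1 adjusted p = 0.055 and adjusted p = 0.068. Without stage 31 replicate 1 the lens list had adjusted p = 0.069. Heart (8 of 21 higher, 1 lower, 8 and 0 adjusted over the list alone, median log2 change 0.96, or 0.20 with 50 units added, adjusted p = 0.21), kidney (9 of 19 higher, 3 lower, 9 and 4 adjusted over the list alone, median log2 change 0.62, adjusted p = 0.29) and vascular genes (5 of 11 higher, 2 lower, median log2 change 0.27, or 0.06 with median centring, adjusted p = 0.41) did not pass as lists. Under poly-A scaling these 3 medians were 1.56, 1.22 and 0.87, and with median centring the heart list was called (adjusted p = 0.038). The atrial myosin light chain myl4 rose at least 4.76-fold, the renal fxyd2 at least 6.71-fold and the endothelial claudin cldn5 at least 2.94-fold. The cement and hatching gland genes agr2 (13560 and 11010 units), dlx3 (2334 and 1300 units) and pitx1 (326.6 and 366.8 units) were not called at stage 31. With 50 units added to each signal agr2 and dlx3 were called lower (adjusted p = 0.0057 and adjusted p = 3.8e-09). Under poly-A scaling pitx1 was called higher (log2 change 0.77, adjusted p = 0.030).

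Maternal genes (24 of 43 lower, 3 higher, 25 and 3 adjusted over the list alone, median log2 change -0.86, adjusted p = 5.0e-05) and early mesendoderm genes (42 of 78 lower, 3 higher, 43 and 3 adjusted over the list alone, median log2 change -0.98, adjusted p = 6.3e-07) fell further. Their medians were -0.41 and -0.57 with 50 units added, and -0.26 and -0.38 under poly-A scaling. The gene gs17 fell from 657.2 units, at least 3.97-fold. The pluripotency factor gene pou5f3.1 fell from 450.1 units, at least 2.72-fold, and gad1.2 from 3091 units, at least 18.7-fold. Epidermal genes (17 of 32 lower, 1 higher, median log2 change -0.59, adjusted p = 5.8e-05) and motile cilia genes (29 of 47 lower, 2 higher, median log2 change -0.49, adjusted p = 2.1e-05) were lower relative to other genes. Under poly-A scaling these medians became 0.02 and 0.11. Chromatin genes were called lower (18 of 34 lower and 7 higher, adjusted p = 0.037), with a median of -0.21 that became 0.39 under poly-A scaling. That call was lost with an estimated correlation (adjusted p = 0.14) and without stage 31 replicate 2 (adjusted p = 0.080). Ribosomal protein genes were called upward by the test (adjusted p = 0.0030) with 35 of 69 higher and 1 lower, although their mean minus that of the other genes was -0.06. Their median of 0.16 became -0.05 with median centring, and with an estimated correlation the call was lost (adjusted p = 0.60).

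There were 12257 calls, 6304 higher and 5953 lower. Of these 51.4% were higher, against 93.5% under poly-A scaling and 34.0% with median centring. Of 13 list calls, 7 held with an estimated correlation.

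From stage 31 to stage 48, from the tailbud embryo to the feeding tadpole, genes of the pancreas and the intestine and stomach lists rose. Of 43 pancreas genes in the list 16 were tested, with 14 higher and 1 lower (median log2 change 8.62, or 6.87 with 50 units added, adjusted p = 9.0e-05). The chymotrypsin-like ctrl was at 20610 units, at least 124-fold higher, and the amylase amy2b at 10770 units, at least 65.0-fold higher. The proteases ctrc and cela1.5 were at least 108-fold and 85.3-fold higher. Intestine and stomach genes, 19 of 56 tested, were higher in 16 cases and lower in 1 (median log2 change 5.07, adjusted p = 3.3e-05). Of these tm4sf4 was at 8079 units, at least 48.8-fold higher. Liver genes were higher in 33 of 48 and lower in 2 (median log2 change 2.14, adjusted p = 7.8e-06), with the apolipoprotein apob at 9450 units, at least 57.0-fold higher.

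Retina genes rose, with 18 of 25 higher and 3 lower (median log2 change 3.51, adjusted p = 1.5e-04), among them the arrestin sag at 4730 units, at least 28.5-fold higher, and the cone opsin opn1sw at least 8.24-fold higher. All 9 lens crystallin list genes tested, of 30 in the list, were higher (median log2 change 3.19, adjusted p = 0.0055), a call lost with an estimated correlation (adjusted p = 0.072). The crystallin crybb1 went from 642.4 to 6883 units with a log2 change of 3.42 and SE 0.84 (n = 2 per stage). Blood genes were higher in 13 of 20 and lower in 4 (median log2 change 1.08, adjusted p = 0.024), and hba2 went from 891.6 to 19370 units. Immune genes were higher in 14 of 24 and lower in 4 (median log2 change 1.80, adjusted p = 8.5e-04), such as the chemokine cxcl12 at 1453 units, at least 8.77-fold higher. Cartilage genes were higher in 15 of 25 and lower in 1 (median log2 change 1.201, adjusted p = 0.0067), with the small proteoglycan epyc at 381.1 and 3830 units. Pituitary and hormone genes were higher in 10 of 11 and lower in 0 (median log2 change 2.15, adjusted p = 5.2e-04).

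Neuronal genes were called higher (23 of 39 higher and 2 lower, median log2 change 1.19, adjusted p = 3.4e-04), and so were skeletal muscle genes (18 of 48 higher and 8 lower, median log2 change 0.47, or 0.25 with quantile normalization, adjusted p = 0.021). The muscle call was lost under poly-A scaling (adjusted p = 0.070), while the list's mean minus that of the other genes stayed at 0.70. Oxidative phosphorylation genes rose, with 52 of 58 higher and 2 lower. Their median log2 change was 0.61 (adjusted p = 1.5e-12, adjusted p = 0.031 with an estimated correlation). Heart genes (10 of 21 higher and 3 lower, median log2 change 1.197, adjusted p = 0.027) and ribosomal protein genes (63 of 69 higher and 2 lower, median log2 change 0.27, adjusted p = 3.1e-08) were called higher. Both calls were lost with an estimated correlation (adjusted p = 0.10 and adjusted p = 0.32). The ribosomal median of 0.27 became -0.02 with quantile normalization.

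Cell cycle genes fell, with 98 of 106 lower and 0 higher (98 and 1 adjusted over the list alone). Their median log2 change was -1.73 (adjusted p = 1.6e-16, adjusted p = 0.020 with an estimated correlation). The replication licensing gene mcm6.2 went from 3029 to 279.3 units, a log2 change of -3.44 with SE 0.12 (n = 2 per stage), and the mitotic cyclin ccnb2 fell from 1060 units, at least 5.78-fold. Chromatin genes fell in 29 of 34 cases and rose in 3 (median log2 change -1.17, adjusted p = 1.9e-05). Motile cilia genes were lower in 35 of 47 and higher in 3 (median log2 change -0.76, or -0.38 under poly-A scaling, adjusted p = 0.028), a call lost with an estimated correlation (adjusted p = 0.24). Without stage 31 replicate 1 the call was lost (adjusted p = 0.061), and without stage 48 replicate 1 as well (adjusted p = 0.0555). Among single genes, astl3a.1, an astacin protease, fell from 7841 units, at least 42.8-fold. The elongation factor eef1a1o fell from 7534 units, at least 41.1-fold, and lin28a, an RNA-binding regulator of developmental timing, from 743.7 units, at least 4.06-fold. Maternal, early mesendoderm, neural plate, neural crest, vascular, epidermal, kidney and hox genes did not pass as lists, with adjusted p from 0.074 to 0.99. The maternal, neural plate and hox lists were called lower under poly-A scaling, the neural plate and hox lists also with 50 units added, and the kidney list was called higher with 50 units added and with a filter at the 75th percentile. For the mesendoderm and epidermal lists the test pointed upward while the medians were -0.21 and -0.11, or 0.17 and 0.27 under poly-A scaling.

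Between stages 31 and 48 limma called 16243 probe sets, 6946 higher and 9297 lower. Of these 42.8% were higher, against 61.4% under poly-A scaling. Of 17 list calls, 13 held with an estimated correlation.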

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

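The test of the hybridisation controls was chosen after the fall of the poly-A controls was seen, as was the scaling to those controls. The signal of the poly-A control RNA, on probe sets that no comparison of embryonic genes uses, changed by -1.78 on the log2 scale between stage 11 and stage 48, from 649 to 188 units over 12 probe sets. Hybridisation, staining, scanning or the scaling of arrays would have to lower the hybridisation controls as well, by at least 0.5 of that fall. These changed by -0.34, which argues against them as the whole cause, although the distance from the bound only just exceeds the largest replicate difference of the hybridisation controls, 0.54. Stage 11 was the highest stage of both kinds of control. At stages 2 and 48 the poly-A mean was 574 and 188 units, and the hybridisation mean was 2868 and 2827 units. Uneven spiking from sample to sample is argued against too, since replicates of a stage differed by at most 0.37, under the bound of 0.89. The 4 spiked transcripts fell alike, the farthest 0.14 from their mean. A rising share of embryonic poly-A RNA in the labelled RNA may give this, but a change of spike amount by stage would give the same. These cannot be told apart, because how the control RNA was added is not given in the sources used here, and a spike stock used for a stage goes with that stage.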

How the results depend on the processing

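Scaling to poly-A controls and array weights by stage were chosen after seeing the data. The count over the 15 stages stayed within 1.5 times its value in all settings except a filter at the 75th percentile, which tests fewer probe sets and gave 14695, and 12341 for stages 11 to 21. Stricter calls lower the counts by construction. With an adjusted p under 0.01 there were 4900 calls for stages 2 to 5, 4828 for 17 to 19, 2055 for 19 to 21, 2563 for 21 to 23, 3283 for 26 to 28, 2863 for 28 to 31 and 4066 for 31 to 37-38. With a 2-fold threshold the 5 intervals had 1675, 8333, 11822, 3989 and 8551 calls, and the steps from stage 5 on had 2977, 6532, 7727, 1958, 1363, 436, 780, 1191, 550, 803, 1129, 1181 and 3089. With log2 of signal plus 50 the step from stage 28 to 31 had 7558 calls, and the cause was not tested. Under poly-A spike-in scaling, counts were 4198 for stages 2 to 5, 5462 for 5 to 9, 4339 for 13 to 17, 1444 for 21 to 23, 2325 for 26 to 28, 2193 for 28 to 31, 4344 for 31 to 37-38 and 2956 for 37-38 to 43, and the cause was not tested.

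Leaving out 1 array, where the lone array of a stage is assumed to vary like the other groups, gave 4948 to 5923 calls for stages 17 to 19, 1702 to 3233 for 19 to 21, 2764 to 3364 for 21 to 23, 3553 to 4178 for 26 to 28, 2729 to 3593 for 28 to 31 and 4084 to 4747 for 31 to 37-38. The lowest counts were without stage 19 replicate 2, stage 19 replicate 1, stage 21 replicate 1, stage 26 replicate 1, stage 31 replicate 1 and stage 31 replicate 2, in that order. The other counts stayed within 1.5 times.

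With an estimated inter-gene correlation 0 lists were called for stages 2 to 5, 8 for 11 to 21 and 7 for 21 to 31. With poly-A spike-in scaling 5 lists were called for stages 2 to 5 and 16 for 5 to 11. With fry, which tests a list alone and not against other genes, 12, 25, 24 and 22 lists were called in the first 4 intervals. Its direction was opposite to camera's, which did not call them, for vascular endothelium in stages 2 to 5 (mean log2 change of the list alone -0.02, minus that of other genes -0.0757), neural crest in 21 to 31 (0.15 and -0.0578), early zygotic mesendoderm in 31 to 48 (-0.54 and -0.55) and epidermis in 31 to 48 (-0.41 and -0.42). The sign of the first value is that of fry. Sign changes that neither setting called occurred in 68 list tests over 22 combinations of list and interval and in 5 tests of 3 named genes, and were not counted as reversals. Differences of replicate 1 minus 2 did not correlate between stages (r -0.06 to 0.04). Noise of dim probe sets can hide a pairing, so none is excluded. A replicate block gave 7437, 15655, 18606, 12217 and 16220 calls. Called lists lost their call with a filter at the 75th percentile (histones and chromatin in 3 intervals, kidney in 5 to 11, heart in 11 to 21, pituitary in 21 to 31), with quantile normalization (histones and chromatin in 3 intervals, liver in 11 to 21, pituitary in 21 to 31, ribosomal proteins in 31 to 48), with median centring (histones and chromatin in 5 to 11, ribosomal proteins in 21 to 31) and without probe sets ending in _s_at or _x_at (blood in 21 to 31). Under poly-A scaling the losses were histones and chromatin in 3 intervals, neural crest, heart and liver in 11 to 21, muscle, lens and pituitary in 21 to 31, and muscle and heart in 31 to 48. The pituitary list of 21 to 31 was also lost with the mean of all probe sets per gene, no filter and 50 units added, and histones and chromatin of 2 to 5 with that mean. Lists not called before gained a call under poly-A scaling: neural crest, retina and cartilage in 2 to 5, neuronal, muscle, heart, vascular, liver, retina, cartilage and hox in 5 to 11, epidermis in 11 to 21, neural plate and hox in 21 to 31, and maternal, neural plate and hox in 31 to 48. Apart from fry, other settings over all 30 arrays gave calls to cartilage in 21 to 31 (8 settings), epidermis in 11 to 21 (5), liver in 5 to 11 (4), hox in 5 to 11 and kidney in 31 to 48 (2 each), and in 1 setting each kidney in 2 to 5, heart, neural plate and hox in 21 to 31, and neural plate and hox in 31 to 48. Leaving out 1 array gave calls to kidney and retina in 2 to 5, liver in 5 to 11 and epidermis in 11 to 21. Among named genes that were not called, dlx3 and agr2 for stages 21 to 31 gained a call with 50 units added and pitx1 under poly-A scaling. Among named genes of stages 2 to 5, kpna7, zp4, nodal3.1, mespa, lmnb3 and anp32a lost their call in some setting, and the other named genes that were called kept it in all settings run. The replicate SD was 0.52 at stage 2 and 0.27 at stage 43, while the median absolute difference between replicates was 0.12 at both.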

Other observations

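The comparison of replicate spread by signal level and the correlation of mitochondrial with nuclear transcripts were chosen after those values were seen, and the gene pairs named for diverging copies were chosen after their values were seen. The other tests were written down before their results were seen. Transcripts encoded by the mitochondrial genome, as a mean of 11 probe sets, were lowest at stage 17, at -0.58 on the log2 scale from their mean over stages, and highest at stage 48, at 0.51. Not every probe set followed this mean, and some had their lowest signal at earlier or later stages. The nuclear oxidative phosphorylation list had its lowest median at stage 11 (-1.09) and its highest at stage 48 (1.46). Across the 15 stage means the 2 courses correlated (Pearson's r 0.81, permutation p = 3.9e-04; Spearman's rho 0.80, permutation p = 6.3e-04; r 0.79 without stages 48 and 17), though neighbouring stages are not independent samples. This goes with a shared course over the whole series. It cannot test whether the groups move apart around the dip at stage 17, because a shared late rise can give such a correlation by itself. From stage 13 to 17 the mitochondrial mean went from -0.22 to -0.58 and the nuclear median from -0.69 to -0.65.

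Xenopus laevis carries L and S copies of many genes from an ancient genome duplication. For 1679 pairs in which both copies had their own tested probe set, the stage means of the copies correlated with a median r of 0.82 across the 15 stages, against at most 0.08 in 100 random re-pairings, and 52.4% of pairs had r above 0.8. That copies share their time course may reflect shared regulation. Probe sets that hybridise to both copies stay an open explanation: leaving out those ending in _s_at or _x_at left 0.998 of the correlation, but it took away few pairs (1722 to 1679), so it decides nothing, although the bound of 0.8 set beforehand against this explanation was met. Probe sequences were not used here. Among 1052 pairs whose copies both ranged over 4-fold and peaked above 200 units, 64 had r under 0. The L copy of ccng1, cyclin G1, peaked at stage 48 with 11150 units and the S copy at stage 2 with 2487 units (r -0.75), and the autophagy gene atg16l1 peaked at stage 23 for L with 2481 units and at stage 9 for S with 1815 units (r -0.91).

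Replicates of stage 2 differed more than those of stage 31, with a replicate SD of 0.52 against 0.29 on the log2 scale. A candidate explanation is that more probe sets are dim early: 20.6% of tested probe sets were in the lowest of 10 bins of signal at stage 2 and 5.62% at stage 31, and within bins the median ratio of the SDs was 0.90. The stage 2 replicate difference had a correlation of 0.020 across probe sets with the change from stage 2 to stage 5. This met the bound set beforehand against replicates collected at slightly different ages. It cannot exclude a slight difference in age, because replicate noise dilutes such a correlation. The replicate SDs of stages 2 and 5 were 0.52 and 0.49, against a root mean square log2 change of 0.73 between them.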
